A study of Rattus norvegicus with 20 samples.

How the data were processed

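Values came from 20 Affymetrix rat arrays of subplate neurons, 5 control and 5 cocultured arrays at 24 h and at 96 h. Per the labels' protocols, 100 ng of RNA, generally from 6 pooled coverslips, was amplified through 2 rounds before labelling, 22100 subplate cells were plated per well and feeder wells held 650000 cells. The labels call the replicates biological.

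The deposited values are linear ratios, per the file headers RMA values over all 20 arrays divided by each gene's median. Per the submitters' processing notes RMA and MAS5 were used, with no role or version given, and the chip definition is not given in the sources used here. The ratio was checked on the file: the median over the 20 arrays was 1 within 0.001 for 31069 of 31099 probe sets. A second deposited table held the authors' average ratio per group for 17243 probe sets, which per the file headers were called present in 10 of 20 arrays, with gene symbols and Entrez identifiers; the averages equalled geometric means recomputed from the arrays within 0.00094. No level of a gene can be read from ratios, so no filter on dim signals beyond these present calls was possible. Nor could the brightest probe set be chosen, and absolute signal over background is unknown.

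Ratios were turned to log2 and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 20 arrays in a single model and 16 residual degrees of freedom. Benjamini-Hochberg adjustment ran over 31042 probe sets, after 57 control probe sets were left out, at adjusted p under 0.05. The planned treatment of values that are not on a log2 scale, scaling to 1 median and flooring at the 5th percentile (a ratio of 0.689), would have removed falls, and was run as an alternative. Probe sets were named through the deposited annotation, with symbols updated by the RefSeq table of assembly GRCr8, used for names alone: 11143 by Entrez identifier, 24 by accession and 165 by symbol, while 9 kept the deposited symbol. A further 216 matched several genes and 5634 none, and these were not named. The 11341 named probe sets stood for 8109 genes, of which 2281 had several. A gene's value was the mean log2 value of its probe sets, fitted and adjusted over the 8109 genes, in place of the planned brightest probe set, and probe sets that disagree are given beside the gene.

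Gene lists, 20 of pathways and 10 of cell types, were fixed before the data were examined, and 28 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. The lists of endothelial cells and pericytes and of Cajal-Retzius cells, with 4 measured genes each, were not tested. Some genes stand in several lists (Fabp7 and Slc1a3 in radial glia and astrocyte). Camera with an estimated correlation and fry were run beside it. Genes named in the text follow a rule fixed at the same time: for each coculture effect and for time in controls, the 12 largest rises and 12 largest falls among genes past the threshold with at least 4 of the 5 arrays beyond the mean of the comparison group; for the interaction the 5 largest in each direction; and up to 4 members of each list with the smallest p. Some genes that this rule names are not reported here.

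Same-numbered arrays deviated together: the correlation of deviations from the group means was 0.243 or more in all 30 same-number pairs, with a median of 0.524 against -0.23 in other pairs, and 17 of 20 arrays were closest to their own number. Some pairs of different numbers correlated as strongly. The correlation was 0.74 between cocultured replicate 2 at 24 h and cocultured replicate 3 at 96 h. For control replicate 3 at 24 h and control replicate 4 at 96 h it was 0.65. Others were far below 0, as cocultured replicate 2 at 24 h with cocultured replicate 5 at 96 h (-0.80). The deviations thus did not part cleanly by number. The main fit held no term for the replicate number, so its standard errors and p-values ignore any pairing. With the number as a random block the estimated correlation was 0.527. A fit with the number as a block, which takes the numbers to pair the samples, is given where it changes a call or moves a count by over 1.5 times. Counts of list members are an exception and are all from the unblocked fit. Alternatives were the block as a fixed or random term, only the groups compared, a robust prior, array weights, the authors' expressed list, equal array medians, cyclic loess, at least 1.5-fold change, 1 value per gene and each array left out. After the data were seen, fits with the hybridisation controls as a covariate, without the 3 arrays of widest spread, without replicate 5, with the floor, with the first probe set of each gene, and with an estimated correlation in the blocked and covariate fits were added.

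The pipeline was tested for the effect at 24 h on simulated data with the residual spread of each probe set. Of 50 probe sets changed at each size among 31042, 18% were called at a log2 change of 0.5, 64% at 1 and 100% at 1.5 and 2, with 6 false calls. A list of 30 genes shifted by 0.5 among 8000 was called, and 0 of the other lists (20 lists in all). Simulated values were independent between genes and between arrays, and a probe set had the same spread in all arrays. In the data the array weights ran from 0.087 to 4.361. The test therefore cannot tell how the pipeline behaves with correlated genes, with arrays of unequal spread or with same-numbered arrays that deviate together. Comparisons of array quality measures used two-sided exact permutation tests over 252 splits.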

Results

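Gene expression was measured on 20 Affymetrix rat microarrays in subplate neurons, an early-born and largely transient population beneath the cortical plate. The neurons were taken from the cortex of rat embryos at day 17 by panning on an antibody to the neurotrophin receptor p75 and were grown on coverslips. Cocultured coverslips stood above a dense layer of cortical feeder cells without touching it, a treatment that induces synapses, and control coverslips stood above wells without cells. Each of the 4 groups, control and coculture after 24 h and after 96 h, held 5 biological replicates. The deposited values were ratios to the median of each probe set over the 20 arrays, so levels of different genes cannot be ranked, and changes are given on the log2 scale with the standard error of the limma fit unless another error is named. For arrays, the number of replicates limits the precision. Standard errors and adjusted p-values of genes are from the unblocked limma fit, with Benjamini-Hochberg adjustment, unless another fit is named.

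The arrays differed in a measure of the hybridisation itself. The bacterial and phage transcripts added before hybridisation (18 control probe sets) had a mean log2 ratio of -0.54 ± 0.67 (SD, n = 5) in controls and 0.32 ± 0.65 in cocultures at 24 h, and of -0.63 ± 0.66 and 0.70 ± 0.64 at 96 h. The difference was 0.86 at 24 h (two-sided exact permutation p = 0.0794) and 1.33 at 96 h (p = 0.0238, exact permutation; the smallest of 252 splits is 0.0079). The control signal was higher in the coculture of all 5 same-numbered pairs at both times. The median log2 ratio of the annotated, expressed probe sets differed by -0.14 (coculture minus control) at 24 h (exact permutation p = 0.206) and by -0.24 at 96 h (p = 0.0238, exact permutation), and that of the other probe sets by 0.13 and 0.27 (exact permutation p = 0.349 and 0.0317). At both times the expressed median was lower, and that of the other probe sets higher, in the coculture of all 5 same-numbered pairs (paired exact p = 0.0625, the smallest that 5 pairs can give).

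**Figure D1:**
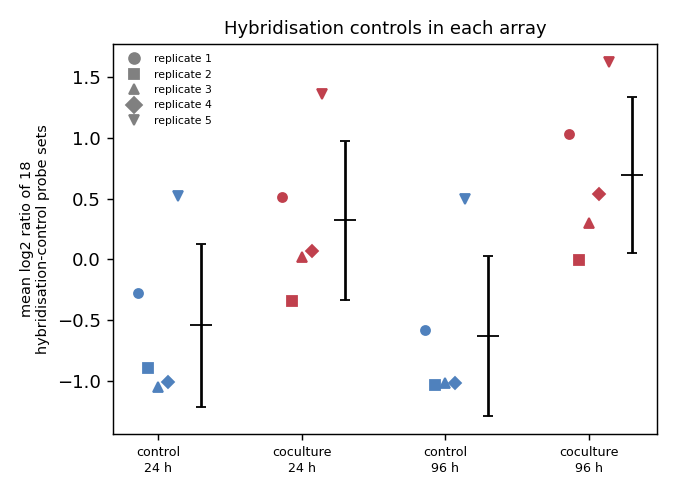
Mean log2 ratio of 18 hybridisation-control probe sets (vertical axis) in each array of the 4 groups (horizontal axis), with replicate numbers as symbols, control arrays in blue and cocultures in red; the bar is the group mean with its SD. Same-numbered cocultured arrays lie above their controls, by 0.86 on average at 24 h and by 1.33 at 96 h.

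The first comparison asked which genes had changed after 24 h above the feeder layer, before the main wave of synapse formation. In cocultured coverslips the lists of radial glia, astrocyte and oligodendrocyte lineage genes were called up, with 8 of 9, 6 of 19 and 4 of 12 members that rose, and activity-regulated genes were called down, with 13 of 24 that fell. With an estimated correlation, the astrocyte and oligodendrocyte lineage lists lost their calls once the hybridisation covariate was added (adjusted p = 0.127 and 0.127), and the astrocyte and activity-regulated lists once the replicate number was added as a block (adjusted p = 0.0572 and 0.18). Fabp7, a fatty acid binding protein of radial glia, was 26.9-fold higher in cocultures (4.75 ± 0.58 on the log2 scale, from -3.85 ± 1.77 to 0.90 ± 0.39, SD, n = 5; adjusted p = 3.08e-05). The transcription factor Fos fell 25.1-fold (-4.65 ± 0.67, adjusted p = 0.000161), and Bdnf, a neurotrophin gene that responds to neuronal activity, fell on the log2 scale (-1.86 ± 0.13, adjusted p = 4.27e-08), with probe sets between -3.07 and -0.64.

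In total 375 of 31042 probe sets rose and 651 fell at 24 h, and with 1 value per gene 225 of 8109 named genes rose and 626 fell. With the replicate number as a block the counts were 3709 and 4970 probe sets. With the hybridisation controls as a covariate the balance turned: 1048 probe sets rose and 596 fell (63.7% up against 36.5%). There, 517 of the 851 called genes kept their call, 177 of 225 that rose and 340 of 626 that fell. With both the block and the covariate 43 of the 851 kept it. The control signal was higher in the coculture of every pair, so that fit leaves little to separate the covariate from coculture. The count moved by over 1.5 times without control replicate 5 (2307), replicate 3 (508), replicate 2 (533) or replicate 4 (580), or without cocultured replicate 1 (642).

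The largest rises at 24 h, besides Fabp7, included Pdgfra, the growth factor receptor of oligodendrocyte precursors (3.86 ± 0.33), the transcription factor Olig1 (3.61 ± 0.33), Bcas1 (2.85 ± 0.35), the RNA-binding protein Zfp36l1 (2.71 ± 0.24) and the progenitor transcription factor Sox2 (2.60 ± 0.22). These were followed by Txnip (2.25 ± 0.25), the replication-associated Pclaf (2.23 ± 0.16), Ndrg2 (2.16 ± 0.36), apolipoprotein Apoe (2.07 ± 0.35) and the hypoxia-inducible factor Epas1 (1.87 ± 0.29). The 12 largest falls, besides Fos, were Acan, a proteoglycan of the neuronal matrix (-2.94 ± 0.39), the calcium-stimulated adenylyl cyclase Adcy8 (-2.74 ± 0.42), Tpbg (-2.50 ± 0.43) and the protocadherin Pcdh20 (-2.50 ± 0.24). Next came the G-protein regulators Rgs2 (-2.13 ± 0.26) and Rgs4 (-2.11 ± 0.24), the stress transcription factor Atf4 (-1.95 ± 0.30), Cadps2 (-1.90 ± 0.25, with probe sets at -3.08 and -0.73), Opn3 (-1.90 ± 0.25), the phosphatase Dusp1 (-1.88 ± 0.30) and Scg2, a granin (-1.87 ± 0.57). All 5 cocultured arrays lay beyond the mean of the 5 controls for each of these. Adjusted p-values ran from 4.27e-08 for Pclaf to 0.0412 for Scg2. Scg2 lost its call with the hybridisation covariate (adjusted p = 0.185) and had an adjusted p of 0.123 without cocultured replicate 5.

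Of the radial glia and intermediate progenitor genes, 8 of 9 measured members rose and 0 fell, or 8 and 0 adjusted over the list alone at 24 h. The median change was 1.37 (camera adjusted p = 3.31e-15; adjusted p = 0.00314 with an estimated correlation). Ptprz1 rose by 1.73 ± 0.21 and Notch1 by 1.56 ± 0.20. Of the astrocyte genes, 6 of 19 measured members rose and 0 fell, or 9 and 0 adjusted over the list alone. The median change was 0.43 (camera adjusted p = 2.89e-10; adjusted p = 0.00647 with an estimated correlation, but 0.0572 with the block too). The glutamate transporter Slc1a3 rose by 1.37 ± 0.21, though its probe sets ranged from -0.04 to 2.79. Of the oligodendrocyte lineage genes, 4 of 12 measured members rose and 0 fell, or 4 and 1 adjusted over the list alone. Their median was 0.14 (camera adjusted p = 2.63e-07; adjusted p = 0.00576 with an estimated correlation). The cell division list rose (camera adjusted p = 3.79e-08; adjusted p = 0.000215 with an estimated correlation): 8 of 22 measured members rose and 0 fell, or 10 and 0 adjusted over the list alone, among them Rrm2 (1.55 ± 0.23), Cdk1 (1.12 ± 0.18) and Ube2c (0.79 ± 0.13). Genes of GABAergic interneurons rose as a list (median 0.37, camera adjusted p = 5.33e-06; adjusted p = 0.00925 with an estimated correlation). Of these, 3 of 14 measured members rose and 0 fell, or 4 and 0 adjusted over the list alone, namely Sox6 (1.28 ± 0.20), Ackr3 (1.09 ± 0.23) and Dlx1 (0.86 ± 0.19). Of these lists, radial glia and cell division kept their call with the hybridisation covariate and an estimated correlation (adjusted p = 0.031 and 0.00794), and astrocyte, oligodendrocyte lineage and interneuron genes did not (adjusted p = 0.127, 0.127 and 0.169).

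The activity-regulated list was called down at 24 h (median -0.67, camera adjusted p = 2.83e-06; adjusted p = 0.0275 with an estimated correlation, but 0.18 with the block too). Of these, 0 of 24 measured members rose and 13 fell, or 0 and 14 adjusted over the list alone, including Klf4 (-1.49 ± 0.19) and the neuropeptide precursor gene Vgf (-1.63 ± 0.22). Of the genes of cholesterol synthesis and uptake, 0 of 32 measured members rose and 21 fell, or 2 and 24 adjusted over the list alone. The list median was -0.70 (camera adjusted p = 1.3e-07; adjusted p = 0.285 with an estimated correlation). The falls included Ebp (-1.19 ± 0.16), Sc5d (-1.33 ± 0.21), Lss (-0.98 ± 0.16) and the sterol sensor Insig1 (-1.03 ± 0.17). Of the genes of the integrated stress response and amino acid supply, 1 of 27 measured members rose and 16 fell, or 1 and 19 adjusted over the list alone. Across the list the median was -0.57 (camera adjusted p = 1.03e-05; adjusted p = 0.285 with an estimated correlation). Falls included Chac1 (-1.08 ± 0.18), Psph (-1.52 ± 0.27) and the amino acid transporter subunit Slc3a2 (-0.93 ± 0.17). Of the oxidative phosphorylation genes, 0 of 55 measured members rose and 3 fell, or 0 and 2 adjusted over the list alone. At the list level the median was -0.41 (camera adjusted p = 0.00132; adjusted p = 0.784 with an estimated correlation). With the hybridisation covariate the list was not called (median -0.03, adjusted p = 0.199). The median of all named genes was -0.19 at 24 h, and -0.06 after cyclic loess.

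The synapse lists were not called at 24 h. Counts of members come from the unblocked fit, which called 851 named genes against 3876 with the replicate block. Few calls among members therefore do not show that the members were unchanged. Of the presynaptic vesicle and active zone genes, 0 of 39 measured members rose and 4 fell, or 0 and 5 adjusted over the list alone. The median change was -0.32 (camera adjusted p = 0.263). Of the excitatory postsynapse genes, 4 of 33 measured members rose and 5 fell, or 6 and 6 adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.161). The AMPA receptor auxiliary subunit Cacng8 rose (0.86 ± 0.17), and the scaffold Homer1 fell (-0.73 ± 0.17). Of the inhibitory synapse genes, 2 of 17 measured members rose and 1 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.869). Of the synaptic adhesion genes, 0 of 32 measured members rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.24). Trophic factors and synaptogenic signals were called higher than other genes (median 0.08, camera adjusted p = 0.000862; adjusted p = 0.0929 with an estimated correlation, but 0.0142 with the block too, where the list was called). Of these, 7 of 35 measured members rose and 3 fell, or 8 and 3 adjusted over the list alone, among them Wnt7a (1.17 ± 0.23). The lists of TGF-beta and BMP response (median -0.07, below 0 though called up, camera adjusted p = 0.0349, blocked 0.0527; adjusted p = 0.115 with an estimated correlation), microglia and macrophage (0.24, 0.0225; adjusted p = 0.285 with an estimated correlation) and meningeal fibroblast genes (0.13, 0.00652; adjusted p = 0.117 with an estimated correlation) were also called up. These 3 were called neither with the hybridisation covariate (adjusted p = 0.834, 0.495 and 0.762) nor after cyclic loess (adjusted p = 0.478, 0.127 and 0.0932). Of the subplate neuron markers, 0 of 16 measured members rose and 0 fell, or 1 and 4 adjusted over the list alone. The list median was -0.21 (camera adjusted p = 0.869). Nr4a2 had a value of -0.74 ± 0.26 (adjusted p = 0.0709, blocked 0.0125) and Ccn2 of -1.51 ± 0.53 (adjusted p = 0.0698, blocked 7.73e-07). The cortical layer neuron list had a median of 0.14 (camera adjusted p = 0.0576) and was called up after cyclic loess (median 0.25, adjusted p = 0.0405). The remaining lists were not called at 24 h, with medians of -0.29 for unfolded protein response and heat shock, -0.22 for hypoxia and glycolysis, -0.35 for antioxidant, -0.12 for interferon, 0.01 for inflammatory, -0.10 for ERK feedback, -0.20 for axon growth, -0.05 for ion channel and -0.36 for p53 response genes (camera adjusted p from 0.0544 to 0.869). The unfolded protein response list was called down in the blocked fit (adjusted p = 0.0465; adjusted p = 0.386 with an estimated correlation).

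**Figure D2:**
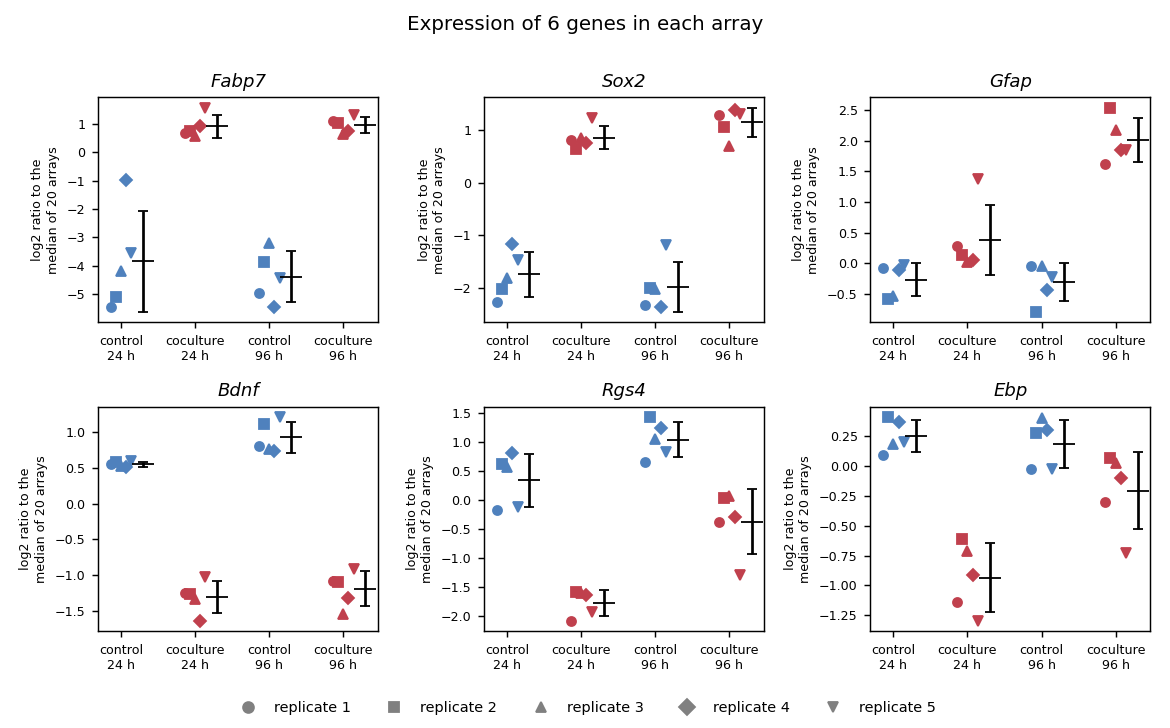
Log2 ratio to the median of the 20 arrays (vertical axes) for 6 genes in each array, with replicate numbers as symbols, controls in blue and cocultures in red, and bars for group means with SD (n = 5). Fabp7 rose by 4.75 at 24 h and 5.34 at 96 h, and Ebp fell at 24 h (-1.19).

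The comparison at 96 h asked for slower changes. The lists of radial glia, astrocyte and oligodendrocyte lineage genes were called up at this time also, with 8 of 9, 12 of 19 and 6 of 12 members that rose and 0, 1 and 1 that fell. Genes of oxidative phosphorylation fell in 47 of 55 measured members, at a time when 3359 of 8109 named genes fell. That list was not called with an estimated correlation (adjusted p = 0.489 with an estimated correlation), and its median went from -0.82 to -0.23 with the hybridisation covariate. Fabp7 was 40.5-fold higher (5.34 ± 0.58, adjusted p = 2.05e-06), Apoe 15.7-fold higher (3.97 ± 0.35) and Gfap, the intermediate filament of astrocytes, 4.98-fold higher (2.32 ± 0.24, from -0.31 ± 0.31 to 2.01 ± 0.36, SD, n = 5; adjusted p = 9.05e-07). Bdnf fell (-2.12 ± 0.13), as did Nrn1, a neurite growth protein gene (-1.93 ± 0.16, adjusted p = 8.22e-08).

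At 96 h 4390 probe sets rose and 5547 fell, or 599 and 3359 of the named genes. Of these probe sets, 2926 that rose and 382 that fell lay outside the annotated, expressed ones. Tested on the authors' expressed list alone, 1520 rose and 5315 fell (22.2% up against 44.2%). With the replicate block the counts were 10599 and 8640 probe sets (1056 and 4611 named genes), and with the hybridisation covariate 1661 and 1430 probe sets. The covariate left 926 of the 3958 genes called, 261 of 599 that rose and 665 of 3359 that fell, and 1 was called in the opposite direction. With both the block and the covariate, 3 probe sets rose and 3 fell, and 7 of the 3958 genes stayed called. The median of all named genes was -0.34, which was -0.12 after cyclic loess and -0.01 with the covariate. The count moved by over 1.5 times without control replicate 2 (5482), replicate 3 (5696) or replicate 4 (5654), or without cocultured replicate 1 (5924) or replicate 5 (5652). Between the times 181 genes rose at both (16.6 for independent lists) and 557 fell at both (259.3), and 1 gene was called in opposite directions. The same-numbered arrays deviate together, so the overlap is not from independent samples.

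Other rises among the largest at 96 h included Pdgfra (4.36 ± 0.33), Olig1 (3.71 ± 0.33), Bcas1 (3.65 ± 0.35) and Sox2 (3.13 ± 0.22). Further rises were Zfp36l1 (2.70 ± 0.24), Smoc2 (2.68 ± 0.66), Ptprz1 (2.68 ± 0.21), Txnip (2.59 ± 0.25) and the gap junction protein Gja1 (2.51 ± 0.38). The 12 largest falls were Gpat3, an enzyme of glycerolipid synthesis (-3.00 ± 0.27), Pcdh20 (-2.83 ± 0.24), Scg2 (-2.82 ± 0.57), Pdlim1 (-2.65 ± 0.26), the G-protein subunit Gnai1 (-2.52 ± 0.58) and somatostatin Sst (-2.48 ± 0.44). They also took in Taf10 (-2.41 ± 0.32), Sipa1l2 (-2.31 ± 0.19), the peptide-amidating enzyme Pam (-2.30 ± 0.19), Anxa4 (-2.24 ± 0.28), the guidance cue Slit2 (-2.18 ± 0.21) and Selenoi (-2.18 ± 0.25). All 5 cocultured arrays lay beyond the control mean for each, with adjusted p-values from 1.35e-08 for Sox2 to 0.00361 for Smoc2. With the hybridisation covariate Smoc2 (adjusted p = 0.118), Scg2 (0.0602) and Gnai1 (0.0602) lost their calls.

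Of the radial glia genes, 8 of 9 measured members rose and 0 fell, or 8 and 0 adjusted over the list alone at 96 h. Across the list the median was 1.53 (camera adjusted p = 4.69e-15; adjusted p = 0.0022 with an estimated correlation). Of the astrocyte genes, 12 of 19 measured members rose and 1 fell, or 12 and 1 adjusted over the list alone. At the list level the median was 1.02 (camera adjusted p = 6e-14; adjusted p = 0.0022 with an estimated correlation). Of the oligodendrocyte lineage genes, 6 of 12 measured members rose and 1 fell, or 6 and 1 adjusted over the list alone. The median change was 0.48 (camera adjusted p = 7.18e-08; adjusted p = 0.0026 with an estimated correlation). Cell division genes (median 0.23, but -0.10 after cyclic loess, camera adjusted p = 4.36e-05; adjusted p = 0.0022 with an estimated correlation; 8 of 22 measured members rose and 2 fell, or 8 and 2 adjusted over the list alone) and interneuron genes (0.40, 0.000395; adjusted p = 0.0436 with an estimated correlation) were also called up. Of the interneuron genes, 5 of 14 measured members rose and 3 fell, or 5 and 3 adjusted over the list alone, with Calb2 at 1.63 ± 0.29 and Sst at -2.48. Their mean change was 0.10, and the list lost its call after cyclic loess (adjusted p = 0.108). Of the 13 lists called at 96 h, 9 kept their call with the hybridisation covariate and the preset correlation, and none did with the covariate and an estimated correlation, where radial glia had a median of 1.06 (adjusted p = 0.0525 with an estimated correlation).

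Of the oxidative phosphorylation genes, 0 of 55 measured members rose and 47 fell, or 0 and 49 adjusted over the list alone. Their median was -0.82 (camera adjusted p = 1.22e-06; adjusted p = 0.489 with an estimated correlation). Examples were Ndufs7 (-1.63 ± 0.25), Cyc1 (-0.95 ± 0.16), Cycs (-0.87 ± 0.15) and Atp5f1d (-1.68 ± 0.31). The median of the list was -0.23 with the hybridisation covariate. Of the integrated stress response genes, 1 of 27 measured members rose and 21 fell, or 1 and 23 adjusted over the list alone. The list median was -0.88 (camera adjusted p = 0.000667; adjusted p = 0.455 with an estimated correlation). With the hybridisation covariate the median was -0.31 (adjusted p = 2.93e-06). Falls included Asns, the asparagine synthetase (-1.65 ± 0.21), Slc7a3 (-2.14 ± 0.28) and Psph (-2.02 ± 0.27). Of the activity-regulated genes, 0 of 24 measured members rose and 14 fell, or 0 and 15 adjusted over the list alone. Across the list the median was -0.63 (camera adjusted p = 0.00898, 0.128 with the replicate block; adjusted p = 0.247 with an estimated correlation). Cholesterol genes were not called at 96 h (median -0.39, camera adjusted p = 0.995). Of these, 2 of 32 measured members rose and 14 fell, or 2 and 14 adjusted over the list alone. After cyclic loess the cholesterol list was called up, with a median of 0.13 (adjusted p = 0.0197). Unfolded protein response and heat shock genes were called down (median -0.52, camera adjusted p = 0.0394; adjusted p = 0.697 with an estimated correlation). That call was lost with the hybridisation covariate (median -0.04, adjusted p = 0.242), after cyclic loess (adjusted p = 0.0966) and without the 3 arrays of widest spread (adjusted p = 0.122).

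The presynaptic list was not called at 96 h (median -0.41, camera adjusted p = 0.693). Of its genes, 4 of 39 measured members rose and 19 fell, or 5 and 19 adjusted over the list alone, and the vesicle protein gene Syt4 fell 2-fold. The excitatory postsynapse list (camera adjusted p = 0.087; 6 of 33 measured members rose and 9 fell, or 6 and 9 adjusted over the list alone) and the inhibitory synapse list (camera adjusted p = 0.494; 2 of 17 measured members rose and 6 fell, or 2 and 6 adjusted over the list alone) were not called either. Grin3a, an NMDA receptor subunit, rose by 0.89 ± 0.13. Synaptic adhesion genes were called higher than other genes (median -0.03, camera adjusted p = 0.0101; adjusted p = 0.483 with an estimated correlation), though the median lies below 0 and the call was lost after cyclic loess (adjusted p = 0.097). Of its genes, 3 of 32 measured members rose and 4 fell, or 2 and 4 adjusted over the list alone, with Cadm1 at 0.78 ± 0.18. Trophic factors were called up (median 0.14, camera adjusted p = 0.000244; adjusted p = 0.0609 with an estimated correlation, but 0.0125 with the block too). So were TGF-beta and BMP response (0.05, 0.0295; adjusted p = 0.0967 with an estimated correlation) and meningeal fibroblast genes (0.19, 0.00396; adjusted p = 0.0967 with an estimated correlation, but 0.0379 with the block too). With the hybridisation covariate TGF-beta and BMP response and meningeal fibroblast genes had medians of -0.20 and -0.01 and were not called (adjusted p = 0.629 and 0.793), nor were they after cyclic loess (adjusted p = 0.599 and 0.15). The remaining lists at 96 h, with camera adjusted p of 0.0544 or more, were hypoxia and glycolysis (-0.68), antioxidant (-0.55), interferon (-0.07), inflammatory (-0.06), ERK feedback (-0.21), axon growth (-0.30), ion channels (-0.08), p53 response (-0.37), subplate neuron (-0.13), cortical layer (-0.07) and microglia (0.16), as median log2 changes. Ion channels were called up with the replicate block (adjusted p = 0.0477; adjusted p = 0.117 with an estimated correlation), and cortical layer genes after cyclic loess (median 0.26, adjusted p = 0.0214).

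**Figure D3:**
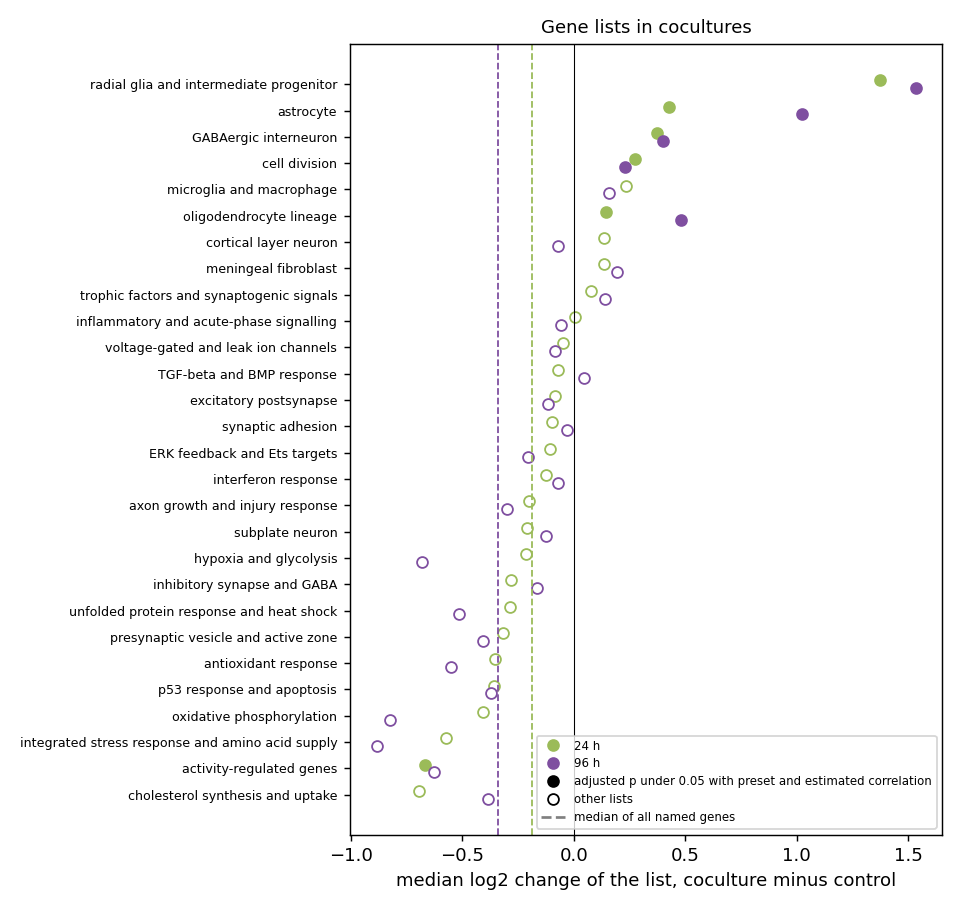
Median log2 change of coculture against control (horizontal axis) of each gene list (vertical axis) at 24 h (green) and 96 h (purple); dashed lines are the medians of all named genes, -0.19 and -0.34. Filled points are lists past the threshold with both a preset and an estimated correlation, among them radial glia at 1.37 and 1.53.

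Whether the coculture effect differed between 96 h and 24 h was tested as an interaction. The lipase Lpl had the largest difference among the genes past the threshold: its coculture effect was lower at 96 h by a log2 value of -2.37 ± 0.30 (adjusted p = 0.00093). Ak4 (-1.28 ± 0.21, adjusted p = 0.0163) and Snx18 (-1.11 ± 0.19) also had lower effects at 96 h, and Garin5a a higher one (0.88 ± 0.15). These 3 lost their calls without at least 1 array, reaching adjusted p = 0.0505 for Ak4 and Garin5a and 0.053 for Snx18. At the level of probe sets 1 had a higher and 5 a lower effect. With the replicate block these were 217 and 768, and after cyclic loess 29 and 13. Leaving out 1 array moved the count by over 1.5 times for 16 of the 20 arrays, to between 2 and 38. The cholesterol list moved up between the times relative to other genes (median 0.33, camera adjusted p = 4.31e-15; adjusted p = 0.16 with an estimated correlation), and no member passed over all genes. The astrocyte list moved up too (median 0.40, camera adjusted p = 8.37e-09; adjusted p = 0.0497 with an estimated correlation, but 0.138 with the block too). So did radial glia (0.35, 6.11e-06; adjusted p = 0.122 with an estimated correlation) and oligodendrocyte lineage genes (0.20, 0.00182; adjusted p = 0.122 with an estimated correlation). Synaptic adhesion (0.04, 0.0056; adjusted p = 0.624 with an estimated correlation) and subplate neuron genes (0.00, 0.0211, blocked 0.0764; adjusted p = 0.245 with an estimated correlation) did as well, though only relative to a median of -0.16 over all named genes. Oxidative phosphorylation moved down (-0.38, 1.92e-06; adjusted p = 0.797 with an estimated correlation). In the blocked fit the trophic factor (camera adjusted p = 0.0757, blocked 0.0178; adjusted p = 0.138 with an estimated correlation and the block) and meningeal fibroblast lists (0.171, blocked 0.0481; adjusted p = 0.187 with an estimated correlation and the block) were called up as well.

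Control cultures were compared between 96 h and 24 h to give the change with time alone. Sst rose by 2.16 ± 0.44, and the early neuronal transcription factor Sox11 fell (-0.85 ± 0.18), both with an adjusted p of 0.0322. The other rises among the 12 largest were Mustn1 (1.88 ± 0.29), Lmcd1 (1.88 ± 0.39), the transcription factor Rreb1 (1.70 ± 0.26), Hist1h4a (1.39 ± 0.25) and Ccdc80 (1.38 ± 0.28). Smaller rises were seen in the endoplasmic reticulum protein Wfs1 (1.30 ± 0.23), Nell1 (1.18 ± 0.24), Man1a1 (0.97 ± 0.17), Rdh10 (0.92 ± 0.18), Pam (0.90 ± 0.19) and Sesn2 (0.90 ± 0.17). The other falls were the proteoglycan Gpc2 (-1.26 ± 0.20), Igfbpl1 (-1.14 ± 0.20), Dock11 (-1.05 ± 0.14), the histone methyltransferase Ezh2 (-0.87 ± 0.16) and Zfp462 (-0.76 ± 0.13). Smaller falls were seen in Tp53i11 (-0.75 ± 0.16), Ttc28 (-0.62 ± 0.12), the progenitor surface protein Prom1 (-0.61 ± 0.13), Plcg1 (-0.59 ± 0.12) and Clic4 (-0.58 ± 0.13). In all 26 probe sets rose and 19 fell, or 23 and 11 named genes, with adjusted p of the genes named up to 0.0435. With the replicate block 555 probe sets rose and 222 fell. All 23 named genes were called there. In the unblocked fit 19 of these lost their call without at least 1 array, Clic4 reaching adjusted p = 0.174. The count of probe sets moved by over 1.5 times without any 1 of 13 of the 20 arrays, to between 6 and 149. The integrated stress response list was called up (median 0.38, camera adjusted p = 1.63e-12; adjusted p = 0.257 with an estimated correlation, but 0.0231 with the block too). Of its genes, 1 of 27 measured members rose and 0 fell, or 11 and 0 adjusted over the list alone. None of the 11 lists called kept its call with an estimated correlation in the unblocked fit. Blocking called cell division (camera adjusted p = 0.122, blocked 0.0351) and meningeal fibroblast genes (0.125, blocked 0.0471) down, and ERK feedback genes lost their call (0.0308, blocked 0.127), and none of these 3 was called with the block and an estimated correlation (adjusted p = 0.177, 0.239 and 0.499).

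The same interval in cocultures gave 129 probe sets that rose and 181 that fell. Fos rose by 3.52 ± 0.67, Egr1 by 1.98 ± 0.45, Gfap by 1.63 ± 0.24 and Apoe by 1.38 ± 0.35, and the receptor Ret fell (-1.11 ± 0.18), as did Sox11 (-1.08 ± 0.18) (adjusted p from 0.00162 for Gfap to 0.0391 for Apoe). Egr1 and Apoe lost their calls without at least 1 array, with adjusted p up to 0.0789 and 0.118. Of the cholesterol genes, 3 of 32 measured members rose and 0 fell, or 9 and 0 adjusted over the list alone. At the list level the median was 0.29 (camera adjusted p = 2.63e-13; adjusted p = 0.174 with an estimated correlation). Subplate neuron genes (median 0.24, camera adjusted p = 2.61e-05; adjusted p = 0.0439 with an estimated correlation, but 0.0764 with the block too) and astrocyte genes (0.27, 9.7e-08; adjusted p = 0.0439 with an estimated correlation, but 0.081 with the block too) were called up. Excitatory postsynapse genes were called up in the blocked fit (camera adjusted p = 0.0662, blocked 0.0409; adjusted p = 0.369 with an estimated correlation and the block). The blocked counts were 1730 and 2688, and after cyclic loess 579 and 468. The count moved by over 1.5 times without 1 of 8 of the 20 arrays, to at most 1423. In a fit of the 2 groups alone 20 probe sets were called. Of the 187 genes called with all arrays 9 kept their call in that fit, and of the 27 called genes that the naming rule took 1 did.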

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

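The tests of explanations in this part, and the reading of the other splits, were all chosen only after the results had been seen. Signal outside the gene comparisons differed between groups: the hybridisation controls were higher in cocultures by 0.863 at 24 h and 1.33 at 96 h. The spread of log2 ratios in cocultured replicate 5 at 24 h was 0.78, far from the other 4 arrays of its group. This was 1 of 24 groups of quality values tested, where chance gives about 1 in 20. Among cocultures at 96 h replicate 5 had a wider spread still (0.86), but replicate 1 was wide too (0.54) and no array was set apart.

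Of 408 groups of 5 arrays (102 genes), 37 held 1 array far from the others, where chance gives about 1 in 20 groups, and 30 of the 37 were replicate 5, 5 replicate 1 and 2 replicate 2. The genes share the same 20 arrays, so the groups are not independent and 1 deviating array can count for many genes. The number 37 is therefore not a test against chance. The log2 ratios of the arrays that stood apart follow. In cocultured replicate 5 at 24 h the values were Pdgfra 2.18, Olig1 2.04, Pclaf 1.75, Ndrg2 2.44, Epas1 2.08, Mustn1 0.05, Lpl 0.15, Chac1 -0.33, Rrm2 1.65, Nr4a2 -1.23 and Gfap 1.38. In cocultured replicate 5 at 96 h the values were Adcy8 -3.31, Sc5d -1.63, Insig1 -0.94, Chac1 -0.90, Cdk1 1.04, Notch1 1.44, Nr4a2 -1.27 and Nrn1 -1.92. In control replicate 5 at 24 h the values were Selenoi 0.30, Sesn2 -0.51, Rrm2 -0.18, Ndufs7 0.05 and Homer1 -0.13. In control replicate 5 at 96 h the values were Ndrg2 -0.57, Acan -0.21, Selenoi 0.74, Insig1 0.54, Rrm2 -0.33 and Slc7a3 0.57. In cocultured replicate 2 at 96 h the values were Pcdh20 -0.15 and Spry2 -0.19. In cocultured replicate 1 at 96 h the values were Apoe 1.36, Ttc28 -0.65 and Lpl -1.61. In control replicate 1 at 24 h the values were Calb2 -0.95. In control replicate 1 at 96 h the values were Rdh10 0.62.

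The coculture effect differed between 96 h and 24 h, by the interaction test, in Lpl (-2.37), Ak4 (-1.28), Snx18 (-1.11) and Garin5a (0.88). Relative to other genes, the effect differed in the lists of cholesterol (median 0.33), oxidative phosphorylation (-0.38), astrocyte (0.40), radial glia (0.35), oligodendrocyte lineage (0.20), synaptic adhesion (0.0431) and subplate neuron genes (0.0019). The median difference of all named genes was -0.16, and -0.04 with the hybridisation covariate. Synaptic adhesion and subplate neuron genes thus stood out only against that fall, and their own medians hardly moved. Of these 7 lists 1 kept its call with an estimated correlation, the astrocyte genes: in the order above, adjusted p = 0.16, 0.797, 0.0497, 0.122, 0.122, 0.624 and 0.245 with an estimated correlation. With the replicate block the subplate list lost its call (adjusted p = 0.0764), as did the astrocyte list with the block and an estimated correlation (adjusted p = 0.138).

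Most named genes were lower in cocultures at 96 h (median -0.34). Lower sample signal on the cocultured arrays may account for this, since the median was -0.0125 with the hybridisation-control covariate. That fit cannot tell signal from coculture, because the controls moved with the groups and ran against the expressed median. Cocultured replicate 5 at 96 h had a control signal of 1.62 and an expressed median of -0.52. For control replicate 3 at 24 h these were -1.05 and 0.11. Loss of the 5' ends of the RNA stays open, since the 5' minus 3' difference of Gapdh was -0.221 (exact permutation p = 0.127), though that of actin was -0.0823 (exact permutation p = 0.627), under the 0.2 set as a bound. For oxidative phosphorylation genes, signal and coculture cannot be told apart, because the controls moved with the groups. The covariate took the list median from -0.82 to -0.23 (95% bootstrap interval over genes -0.29 to -0.17) and the list kept its call at the preset correlation (adjusted p = 2.93e-06, and 1.04e-09 with the block as well, median -0.63), but with an estimated correlation it was called neither with the covariate (adjusted p = 0.304) nor without it (adjusted p = 0.489 with an estimated correlation). A biological effect of the coculture on these genes stays open too. The bootstrap intervals here and below resample genes and hold no error between arrays, so they do not measure the precision of the coculture effect.

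The radial glia and astrocyte lists were called up in cocultures, where 8 of 9 and 6 of 19 members rose at 24 h, and 8 and 12 at 96 h with 1 astrocyte gene that fell. Lower sample signal as the whole cause is argued against at 24 h for radial glia (median 1.19 with the covariate), with an adjusted p of 0.031 with the covariate and an estimated correlation, but radial glia at 96 h and astrocyte genes at 24 h and 96 h lost that call (adjusted p = 0.0525, 0.127 and 0.0525) as their medians shrank, from 1.53 to 1.06 (95% bootstrap interval over genes 0.63 to 2.74), 0.43 to 0.27 (0.14 to 0.76) and 1.02 to 0.64 (0.18 to 1.66). These 3 were called with the preset correlation and the covariate (adjusted p = 4.34e-09, 1.92e-05 and 1.46e-08), and with the block, the covariate and an estimated correlation (medians 1.94, 1.20 and 1.85, adjusted p = 0.0169, 0.0204 and 0.0169), but that fit leaves little to separate coculture from the covariate (median standard errors of a member 0.76, 0.54 and 0.80 against 0.21, 0.24 and 0.24 with neither), so for these 3 signal as the whole cause stays open. RNA or cells carried over from the feeder layer cannot be told apart from a change in the neurons by the cortical layer neuron genes, which had medians of 0.135 at 24 h and -0.07 at 96 h with members that went both ways (called up after cyclic loess, adjusted p = 0.0405 and 0.0214), and feeder and panned cells both hold cortical neurons. A candidate explanation is that more progenitors and glia divided or survived in cocultures, since the cell division list had an adjusted p of 0.000215 with an estimated correlation, but cell counts were not analysed and how many other cells panning left is unknown.

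The activity-regulated list was called down in cocultures at 24 h, where 13 of 24 members fell. Lower sample signal is argued against as the whole cause, since the list had an adjusted p of 0.00794 with the covariate and an estimated correlation. With the block as well the adjusted p was 0.0204, but that fit leaves little to separate coculture from the covariate and adds no support. With the block and no covariate the list was not called (adjusted p = 0.18 with an estimated correlation). A lower share of neurons and a change in the regulation of these genes cannot be told apart, since the medians of other neuronal lists lay at different distances from theirs. The difference of medians was -0.584 against excitatory postsynapse genes (95% bootstrap interval -1.38 to -0.12 over genes) and -0.802 against cortical layer genes (-1.54 to -0.142), but the intervals reached above 0 for presynaptic (-0.349, -1.10 to 0.178), inhibitory synapse (-0.385, -1.21 to 0.122) and subplate genes (-0.456, -1.26 to 0.113). Both stay open.

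Groupings of the arrays were compared with 100 splits, the real one included, in unblocked fits that ignore the pairing of the replicate numbers. As many probe sets as in the real split were called in 2 at 24 h (1026, highest other 3723), 2 at 96 h (9937, highest other 13649), 2 for time in controls (45, highest other 300) and 3 for the difference (6, highest other 13742), a share under 0.05 in splits that ignore the pairing. The difference rests on few probe sets, which were 2 to 38 on leaving out 1 array. For time in cocultures 6 splits gave as many as the real 310 (highest other 14170), a share of 0.05 or more. At 24 h and at 96 h the other split with as many calls exchanged cocultured replicate 2 with control replicate 5. That split set the arrays of lowest hybridisation-control signal against those of highest. Cocultured replicate 2 had a signal of -0.34 at 24 h and -0.01 at 96 h, and control replicate 5 of 0.52 and 0.50. More probe sets were thus called by a grouping along that signal than by coculture. In the blocked fit, among 16 splits that part as many pairs, the real counts were 8679 at 24 h and 19239 at 96 h against highest others of 441 and 9010, 777 against 0 for time in controls and 4418 against 504 for time in cocultures. The real count was the highest in each, but 16 splits are too few to give a share under 0.05, so under the pairing chance was not put to that test. No blocked splits were run for the difference or for gene lists. For gene lists, 23, 11, 11, 16 and 55 of the 100 splits gave as many calls at 24 h, at 96 h, for time in controls, for time in cocultures and for the difference (real 13, 13, 11, 13 and 7, highest others 15, 14, 15, 18 and 18), so unblocked splits do not exclude chance for the number of lists. In the same order, the other splits called a median of 8, 8, 6, 8 and 7 lists at the preset correlation.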

How the results depend on the processing

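Fits with the hybridisation controls as a covariate, without the 3 arrays of widest spread, without replicate 5, with a floor, with the first probe set of each gene, and with an estimated correlation in a blocked or covariate fit were chosen only after the data were seen. Counts below are probe sets past the threshold at 24 h, at 96 h, for their difference, for time in controls and for time in cocultures, in that order. With the replicate block, which follows the pairing of the numbers, they were 8679, 19239, 985, 777 and 4418, and with a random replicate block 7788, 19399, 373, 624 and 3580. The block ended the calls of TGF-beta and BMP response at 24 h, activity-regulated genes at 96 h, subplate neuron genes for the difference and ERK feedback genes for time in controls, and no other call of a named gene or list, and it added calls of lists given with each comparison. Array weights gave 9887, 17147, 974, 2288 and 3652, the covariate 1644, 3091, 102, 455 and 1851, and the block with the covariate 17, 6, 14, 592 and 172. Rises made up 63.7% of the calls with the covariate at 24 h, against 36.5% without it. The controls were higher in the coculture of all 5 pairs at both times, so the block with the covariate leaves little to separate coculture from the covariate. Leaving out the 3 widest arrays gave 1885, 5969, 122, 330 and 867, and leaving out replicate 5 gave 4746, 15283, 190, 390 and 2136. Fitting only the groups compared gave 637 at 24 h, 84 for time in controls and 20 for time in cocultures. Cyclic loess gave 42 for the difference (69.0% up against 16.7%), 80 for time in controls and 1047 for time in cocultures (55.3% up against 41.6%). Equal medians gave 3 for the difference, as did the floor, with 0% up. The floor also gave 1578 at 24 h and 111 for time in controls (78.4% up against 57.8%), and 1 value per gene gave 3958 at 96 h and 187 for time in cocultures. Leaving out each array gave 508 to 2307, 5482 to 13597, 2 to 38, 6 to 149 and 139 to 1423. These counts moved by over 1.5 times, and apart from fewer arrays or tests the cause was not tested. A robust prior and a 1.5-fold minimum stayed within that factor in all 5 comparisons.

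Of the lists, 13, 13, 7, 11 and 13 were called. An estimated correlation left 6, 5, 1, 0 and 3 in camera, an estimated correlation with the block 5, 7, 0, 1 and 0, with the covariate 4, 0, 0, 1 and 0, and with both 6, 6, 0, 2 and 1. Fry called 0 for the difference, 0 for time in controls and 3 for time in cocultures, and the first probe set gave 7 for time in controls. Leaving out each array gave 10 to 14, 11 to 14, 6 to 11, 6 to 13 and 7 to 16 lists. For comparison, 1419 and 1421 probe sets had an unadjusted p under 0.05 for the difference and for time in controls.

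Directions turned in few results, and the cause was not tested. With the covariate at 96 h, Fbln2 had -0.0132, Lpar1 -0.19 and Tle4 0.21. With the block and the covariate, Stat3 had 0.0137 at 24 h and 0.23 at 96 h, and at 96 h Bmp4 had -0.16, Irf9 0.0183 and Syt4 0.0136. With the first probe set, Etv5 had 0.0749 at 24 h and 0.35 at 96 h. The cholesterol list at 96 h, not called and with a median of -0.39, was called up after cyclic loess with a median of 0.13. The synaptic adhesion list at 96 h turned in fry (adjusted p = 0.884), and the microglia and macrophage list at 24 h turned with the covariate (adjusted p = 0.495) and with the covariate and an estimated correlation (adjusted p = 0.784).

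Not run were the filter on mean level, the intensity trend and the brightest probe set per gene, since ratios hold no levels, and per-array values of the annotated table, which it does not hold. Signal over background cannot be read from ratios, so the limit it sets on dim probe sets is unknown.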

Other observations

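In cocultures between 24 h and 96 h, the interferon response list was called up (median 0.18, camera adjusted p = 0.00648; adjusted p = 0.049 with an estimated correlation), and 1 of 11 measured members rose and 1 fell, or 2 and 1 adjusted over the list alone. With the hybridisation covariate it was not called (adjusted p = 0.18). Nor was it with the block and an estimated correlation, where none of the 13 lists called in this comparison kept its call. The presynaptic list was called up over the same interval in controls (median 0.19, camera adjusted p = 0.0123; adjusted p = 0.589 with an estimated correlation) and in cocultures (median 0.09, camera adjusted p = 0.00648; adjusted p = 0.546 with an estimated correlation), and 1 of 39 measured members rose and 0 fell, or 1 and 0 adjusted over the list alone in cocultures. In controls, the lists of axon growth and injury response (median -0.12, camera adjusted p = 0.0308; adjusted p = 0.589 with an estimated correlation) and cortical layer neurons (-0.10, 0.0123; adjusted p = 0.406 with an estimated correlation) were called down.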
